A study of Mus musculus with 6 samples.

How the data were processed

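The series holds 6 single-cell RNA libraries (10x Chromium 3′ v3.1) of sorted mouse brain cells, 3 WT and 3 Foxf2-ECKO, grouped by the genotype in each sample's labels. Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 against mm10. The annotation version and the intron setting were not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, for 32285 genes and 2 antibody hashtag features, whose counts were kept apart. Of the genes, 32158 matched a GENCODE vM21 (GRCm38) identifier, which gave positions and spans. Depth ranged from 1005462 to 5521493 gene UMIs per library and from 447375 to 3576562 over endothelial cells. Libraries of 1 genotype differed by more than counting noise (chi-square per degree of freedom 3.24 to 8.75), so none was treated as a repeat of another.

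Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept, and 992 of 8137 failed. Scrublet (scanpy 1.11.5, scikit-image 0.26.0) marked 53 doublets (0.651% of barcodes), of which 42 were removed here and the others had failed the filter. All cells were clustered without centring (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). A cluster was named from fixed marker lists where at least 3 markers stood 0.3 (log2) above the other clusters and the mean score was at least 0.5, with 20 CPM added. Endothelial clusters needed only a positive endothelial score above that of each other cell type. Endothelial cells were clustered again after centring per library (15 components, 20 neighbours, resolution 0.2), without sex-linked genes, Foxf2, haemoglobin, interferon, immediate-early, ribosomal and mitochondrial genes. This gave capillary-like (3143 cells), arterial-like (410), venous-like (346) and unnamed (888) classes beside 81 fenestrated-like cells. The names are rebuilt from markers and are not the authors' classes. A mixed cluster of 165 cells with neuronal and endothelial genes was left out of both the endothelial and the non-endothelial cells. The pericyte cluster (376 cells) holds smooth muscle cells, since doubling the resolution parted 52 of them.

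Gene lists, groups, tests, the naming rule for genes and the alternatives not named as added were fixed before the data were examined. The cell filter was set after quality values and the Foxf2 and Tek counts of all barcodes had been viewed. Clustering settings were chosen after several had been viewed, among them an all-cell clustering centred per library and other resolutions for endothelial cells. The thresholds for naming clusters, and 1 revision of the rule for all cells, also followed a look at clusters. These steps came before any test of genotype.

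Counts were summed per library over the cells of a class, with at least 20 cells, and tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood, TMM, filterByExpr by genotype, Benjamini-Hochberg at 0.05). DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it. SE values are the absolute log2 fold change over the root of F and are approximate. The fit without a block was planned as the first one and the fit with the replicate number as a block as its alternative. The replicate numbers come from the sample titles, and the labels do not say what libraries of 1 number share. They were taken to pair the libraries if, after genotype means were removed, log2 CPM of each pair correlated above 0.1. In the first calculation (genes above 20 CPM, prior count 2, 7175 genes) the pairs gave r = 0.117, 0.617 and 0.398, and all 6 libraries were closest to their own number. This calculation was printed in 1 run with the calls of both fits, so the decision to treat the libraries as paired was not made blind to those calls. After them, 15 combinations of gene set and prior count were examined. In 2 of the 15, both with genes above 10 CPM, pair 1 fell below 0.1, and over all 15 it ran from 0.0967 to 0.260. The pairing is marginal for pair 1, and most named genes rest on it, because they were called only with the block.

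The naming rule took called genes with a mean of at least 10 CPM and each Foxf2-ECKO library on 1 side of each WT library. It took up to 12 per direction by fold over all endothelial cells and 6 within a class, without predicted (Gm, Rik) or sex-linked genes. Foxf2 and Tek were always named. Because the fit without a block called fewer than 10 genes and the numbers were taken to pair the libraries, the rule was applied to the blocked fit. For venous-like and arterial-like cells, where that fit also called fewer than 10, the 6 smallest p per direction are named. Vegfc, Car4, Zeb2, Gm10800 and some list members were named after their values were seen. Of the 51 genes called with the block over all endothelial cells, 5 are predicted genes and 20 have overlapping groups.

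Genotype by class was an edgeR F test with the library as a block. The 26 pathway and 22 marker lists were tested with camera (preset correlation 0.01, adjusted over the lists), with an estimated correlation and with fry. The sex-linked list is a check of the animals and was taken out of the adjustment after a first run. Shares of cells and Foxf2 levels were compared by exact two-sided permutation (20 assignments, smallest p 0.1) and within replicate numbers by exact sign-flip tests (8 patterns, smallest p 0.25). The share of cells with a Foxf2 UMI was taken after thinning each cell to 1000 UMIs. Intervals are exact at 95% and hold counting error alone. Counts in non-endothelial cells at first held barcodes that had failed the filter, by an error in the code, and were corrected after those values had been seen.

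Each fit was tested on simulated data with 200 changed genes. Counts were drawn from the means and dispersions of the blocked fit, so the simulated libraries were paired by construction, which favours the block. Over all endothelial cells edgeR recovered 6% of 2-fold and 79% of 4-fold changes without the block and 67% and 94% with it. The blocked fit made 13 false calls among 174, above the nominal share. DESeq2 recovered 15% and 78% and limma-voom 6% and 76%. In capillary-like cells edgeR recovered 19% and 82% without and 71% and 91% with the block (12 false among 174). In venous-like cells it recovered 7% and 68%, and 47% and 82% with the block (7 false among 136). In arterial-like cells it recovered 2% and 64%, and 54% and 77% with the block (8 false among 139). The genotype by class test, with changes in venous-like cells alone, recovered 14% and 64% (13 false among 91).

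Alternatives fixed before the data were seen were other size factors, no filter on low counts, DESeq2, limma-voom, the replicate block, each library or replicate number left out, doublets kept, stricter cells (at least 1000 genes, at most 5% mitochondrial UMIs), thinned libraries, all deposited barcodes, an equal class mix and other clusterings. Added after the data were examined were leaving out the unnamed cluster, removing a trend on gene length, the endothelial share of a library as a covariate, resolutions for all cells, Foxf2 levels without each library, and alternatives of the blocked fits. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.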

Results

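Single cells from whole mouse brain were profiled in 6 libraries, 3 of the genotype WT and 3 of the genotype Foxf2-ECKO, named after the forkhead transcription factor gene Foxf2. The cells had been enriched for the endothelial surface protein CD31 and sorted as viable cells, with doublets and CD11b/CD45-positive microglia gated out. The libraries held 2306, 1724 and 488 barcodes in WT replicates 1, 2 and 3, and 1627, 1494 and 498 in Foxf2-ECKO replicates 1, 2 and 3. Their gene counts summed to 5521493, 4382134 and 1005462 unique molecular identifiers (UMIs) in WT and to 3595756, 3272711 and 1392470 in Foxf2-ECKO. After filtering, 7103 cells were retained, of which 4868 were endothelial by a fixed marker list. Endothelial cells made up 46.0%, 88.2% and 84.1% of the retained cells in WT replicates 1 to 3 and 60.7%, 89.2% and 53.8% in Foxf2-ECKO replicates 1 to 3, which differs within each genotype. Their summed endothelial UMIs ranged from 447375 in Foxf2-ECKO replicate 3 to 3576562 in WT replicate 2. Nothing in the labels says that the libraries came from separate animals. The p-values of single genes and of shares therefore measure the spread between these libraries, which may be technical. The camera p-values of lists at the preset correlation compare a list's genes with the other genes and do not measure that spread.

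The first comparison asked how much Foxf2 RNA remained in the Foxf2-ECKO libraries. Foxf2 (ENSMUSG00000038402, chromosome 13, 31625816 to 31631403, GRCm38) stood at 128 ± 15.8 CPM (UMIs scaled to one depth; SD, n = 3) in WT endothelial cells and at 25.5 ± 8.50 CPM (n = 3) in Foxf2-ECKO endothelial cells. The gene fell with a log2 fold change of -2.23 ± 0.24 (approximate SE; edgeR adjusted p = 0.00125) without a replicate block and of -2.26 ± 0.17 (adjusted p = 3.39e-10) with it. In capillary-like cells Foxf2 was at 142 ± 17.0 CPM in WT and 26.2 ± 13.3 CPM in Foxf2-ECKO. It fell there by 2.23 on the log2 scale with the block. Each endothelial Foxf2-ECKO library lay below each WT library. An exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. The remaining reads do not show how much of the gene was deleted, since 3′ reads of Foxf2 may lie outside the deleted part. Without Foxf2-ECKO replicate 1, Foxf2 missed the threshold in the fit without a block (adjusted p = 0.0814, log2 fold change -2.14). Over that fit's alternatives its adjusted p ran from 7.77e-16 to 1.00. The upper end is over all deposited barcodes, which sum non-endothelial cells too (log2 fold change -2.23). Without both libraries of replicate number 1 the edgeR adjusted p was 0.355.

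With each cell thinned to 1000 UMIs, 10.7 ± 1.37% (SD, n = 3) of WT endothelial cells and 2.62 ± 0.543% (n = 3) of Foxf2-ECKO endothelial cells held a Foxf2 UMI. In all, 201 WT and 168 Foxf2-ECKO cells were too shallow to be thinned. Oligodendrocytes, which should lack Foxf2, gave a background of 0 of 258 thinned cells in WT and 0 of 145 in Foxf2-ECKO, which allow shares of up to 1.16% and 2.07% (3 counts, counting error only). Their median depth was 4450 and 4583 UMIs, against 2094 and 1962 in WT and Foxf2-ECKO endothelial cells. Without thinning, Foxf2-ECKO oligodendrocytes held 0 Foxf2 UMIs among 720090, and Foxf2-ECKO endothelial cells held 141 among 4794472 (29.4 CPM, pooled). Pericytes, the mural cells of capillaries, held 35 Foxf2 UMIs in WT (66.0 CPM, pooled) and 12 in Foxf2-ECKO (47.4 CPM, pooled), of which 10 were from replicate 1. In replicates 1, 2 and 3 pericyte Foxf2 was at 47.6, 87.6 and 59.7 CPM in WT and at 86.8, 20.6 and 0 CPM in Foxf2-ECKO, so pair 1 ran opposite to the others. Over libraries, pericyte Foxf2 was 65.0 ± 20.6 CPM in WT and 35.8 ± 45.4 CPM in Foxf2-ECKO (SD, n = 3; exact permutation p = 0.4), and at this depth a difference was not detectable.

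**Figure D1:**
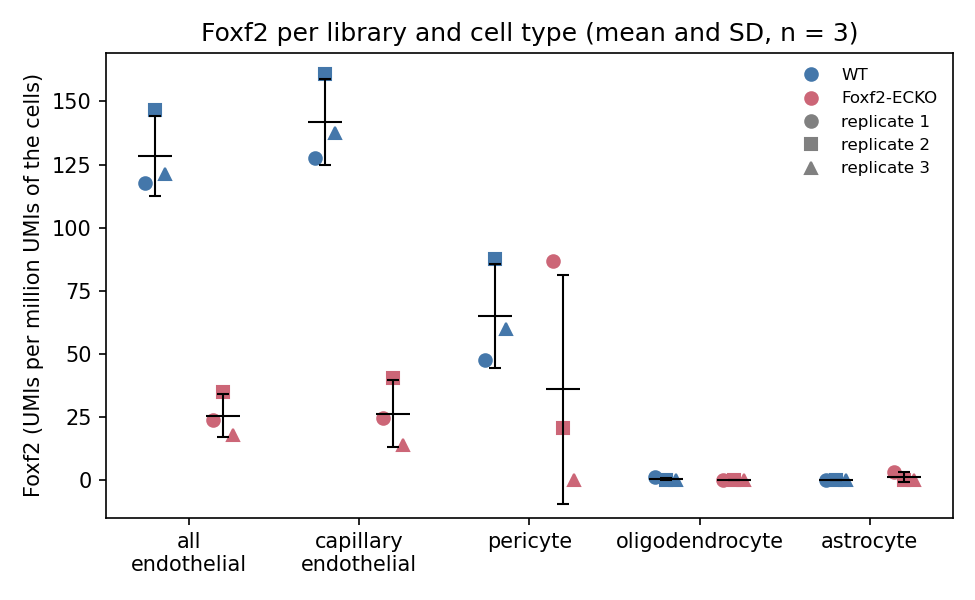
Foxf2 in CPM of the summed cells of each type, with one point per library and bars for the mean and SD of 3 libraries. In endothelial cells the WT libraries lay between 117.5 and 146.5 and the Foxf2-ECKO libraries between 17.9 and 34.7, and oligodendrocytes and astrocytes were near 0.

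The second comparison asked which genes differed between the genotypes over all endothelial cells. Hebp1, a heme-binding protein gene (ENSMUSG00000042770, chromosome 6, 135137522 to 135198022), fell from 41.0 ± 9.99 CPM (SD, n = 3) to 4.22 ± 1.75 CPM. It and Foxf2 were the 2 genes past the threshold without a block (edgeR, adjusted p = 0.00125 each). With the replicate number as a block, a fit whose use was settled after both counts had been seen, 51 of 10229 genes passed, 26 higher and 25 lower in Foxf2-ECKO. Slc16a1, a lactate and monocarboxylate transporter of the blood-brain barrier (ENSMUSG00000032902, chromosome 3, 104638668 to 104658462), fell from 460 ± 64.0 to 217 ± 43.2 CPM, a log2 fold change of -1.10 ± 0.12 (approximate SE; adjusted p = 6.14e-07). Edn1, the gene of the vasoconstrictor endothelin (ENSMUSG00000021367, chromosome 13, 42301476 to 42307990), rose from 443 ± 120 to 747 ± 126 CPM, a log2 fold change of 0.74 ± 0.11 (adjusted p = 5.30e-04). Unc13c, a vesicle priming protein gene, rose from 59.0 ± 11.5 to 155 ± 48.4 CPM and Cdh13, the gene of a membrane-anchored cadherin, from 137 ± 40.6 to 267 ± 97.1 CPM. Tek, the gene of the angiopoietin receptor Tie2 (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976), was at 663 ± 136 CPM in WT and 652 ± 157 CPM in Foxf2-ECKO, with a log2 fold change of -0.06 ± 0.12 (adjusted p = 0.967) that ran from -0.21 to 0.09 when libraries were left out.

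The 12 named genes that fell with the block also held Cdkn2b, an inhibitor of cyclin-dependent kinases (43.8 ± 8.85 to 14.8 ± 4.84 CPM), the cell-surface peptidase gene Dpp4 (44.6 to 18.2 CPM) and the mitochondrial aldehyde dehydrogenase gene Aldh2 (280 ± 53.0 to 175 ± 24.4 CPM). Tmem100, Lysmd2, Rnase4, Cpe, Ivns1abp and Trim16 fell with log2 fold changes between -0.92 and -0.72. The 11 named genes that rose also held the calcium channel gene Cacna1d (7.98 ± 0.848 to 26.6 ± 7.08 CPM), the collagen gene Col8a1 (13.6 ± 0.912 to 38.6 ± 13.6 CPM), the proprotein convertase gene Pcsk5 (15.4 ± 4.72 to 44.0 ± 28.1 CPM, with 76.0 CPM in Foxf2-ECKO replicate 3) and the matrix protein gene Fbln2 (63.6 ± 6.64 to 116 ± 20.6 CPM). Fam102a, Cited4, the noncoding RNA Bc1 and Spata13 rose with log2 fold changes between 0.86 and 1.20. Reads of Rnase4 and Ang, of Trim16 and Fbxw10, and of Slc16a1 and the noncoding Gm43581 and Gm43585 overlap on 1 strand, so their split is uncertain.

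The fit without a block had 236 of 10229 genes at an unadjusted p below 0.05, where 511 would be expected by chance, and the blocked fit 797. DESeq2 called 4 genes and limma-voom 2 without a block. Groups of 3 libraries did not overlap for 7.19% of genes, where chance gives 10%, and for 31 of the 51 genes called with the block. The latter were selected and cannot be read against that share. Libraries carried weight. Without Foxf2-ECKO replicate 1 the fit without a block called 0 genes (Hebp1 adjusted p = 0.0696). Over that fit's alternatives the adjusted p of Hebp1 ran from 2.50e-16 to 1.00, the last over all deposited barcodes, non-endothelial cells included. The fit also called 0 genes without both libraries of replicate number 1, and 5 without Foxf2-ECKO replicate 2. The blocked count was 9 without Foxf2-ECKO replicate 1, 18 without WT replicate 1, 21 without WT replicate 3, 20 without Foxf2-ECKO replicate 3, and 10, 101 and 7 without both libraries of replicate number 1, 2 and 3. Of the 23 named genes, Foxf2, Hebp1, Slc16a1, Unc13c and Cdh13 stayed past the threshold in all 9 such settings, 18 lost it without Foxf2-ECKO replicate 1, and Edn1 had adjusted p-values up to 0.184. The blocked count also moved with the cells summed: it was 19 with stricter cells, 26 with each class at an equal share in every library and 0 over all deposited barcodes. On the same cells DESeq2 with the block called 16.

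**Figure D2:**
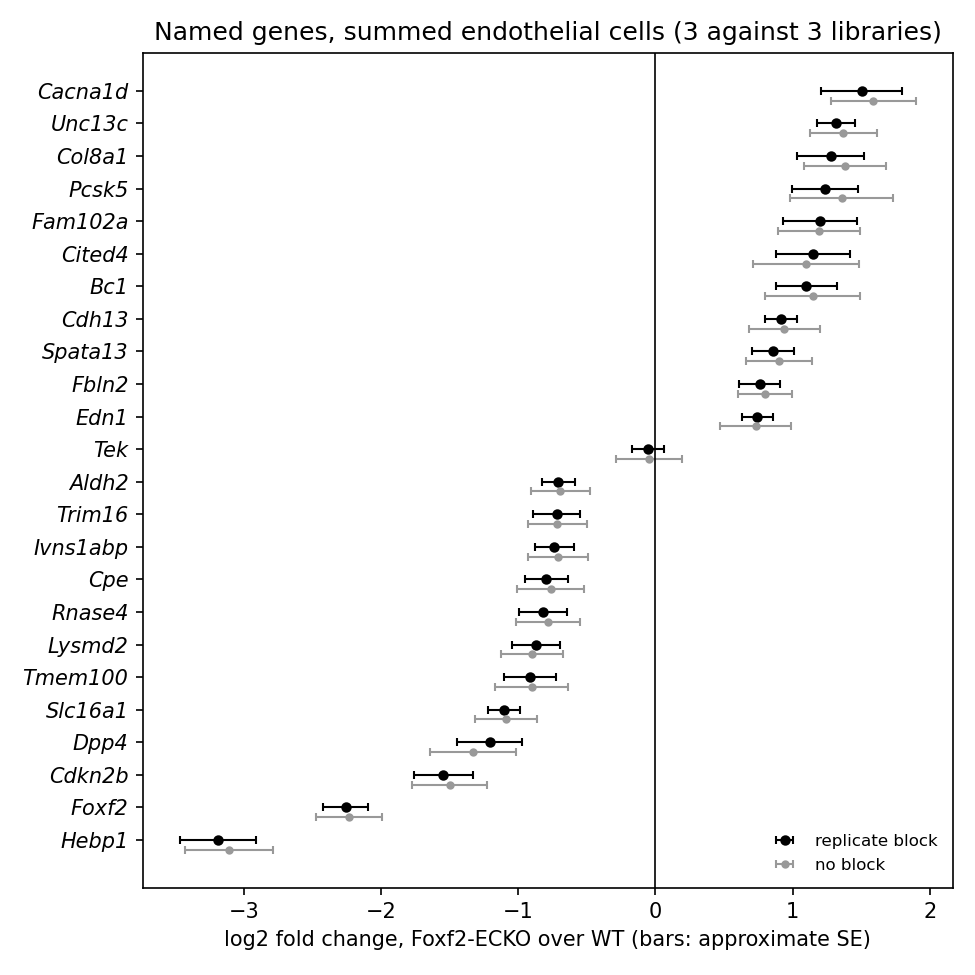
Log2 fold changes (Foxf2-ECKO over WT) of the 23 named genes and of Tek in summed endothelial cells, with approximate SE bars, for the fit with the replicate block (black) and without it (grey). Both fits gave one sign for each named gene, with the lowest at -3.19 for Hebp1, and Tek lay at -0.06.

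The third comparison tested 26 lists of genes, fixed before the data were examined, over all endothelial cells. Among 18 measured genes of arterial identity, 2 rose with the replicate block, Edn1 and the growth factor gene Vegfc (119 ± 51.8 to 202 ± 75.6 CPM; adjusted p = 7.04e-04). In that list 0 fell and the others did not pass. The list as a whole was higher (camera adjusted p = 1.08e-05 with the block and 8.67e-05 without it, median log2 fold change 0.25 with the block), with adjusted p = 0.477 and 0.486 with an estimated correlation. Among 12 genes of capillary identity, 3 fell with the block, Slc16a1, the carbonic anhydrase gene Car4 (689 ± 82.3 to 485 ± 78.0 CPM; adjusted p = 0.0270) and Ivns1abp. In that list 0 rose and the others did not pass. Adjusted over the list alone, 4 of these 12 fell and 1, the transferrin receptor gene Tfrc, rose. The capillary list was lower (adjusted p = 1.68e-04 with the block, median log2 fold change -0.07, mean -0.20; 0.00710 without it), with adjusted p = 0.477 and 0.486 with an estimated correlation. Arterial-like cells were 7.61 ± 0.210% of WT and 10.3 ± 2.48% of Foxf2-ECKO endothelial cells, and capillary-like cells 64.9 ± 5.19% and 57.7 ± 11.4%. These mean shares moved alongside the lists. In replicate number 2 the arterial-like share was not higher in Foxf2-ECKO, with 103 of 1331 cells in WT and 87 of 1161 in Foxf2-ECKO.

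Nuclear genes of oxidative phosphorylation were lower (25 of 26 members negative, 0 called; camera adjusted p = 0.00178 without and 5.07e-06 with the block), with adjusted p = 0.778 and 0.477 with an estimated correlation. All 13 mitochondrially encoded genes had negative fold changes with 0 called (adjusted p = 0.00657 and 1.20e-05), with adjusted p = 0.566 and 0.477 with an estimated correlation. With the block and each library's trend on gene length removed, mitochondrially encoded genes did not pass (0.525). The median mitochondrial share of endothelial cells, a sign of cell quality, was lower in the Foxf2-ECKO library of each replicate number: 3.08 and 3.00%, 4.47 and 3.81%, and 4.80 and 3.91% in WT and Foxf2-ECKO replicates 1, 2 and 3. Basement membrane and matrix genes were higher (adjusted p = 0.00297 and 0.00495), with 0 of 21 called and, adjusted over the list alone, 3 that rose with the block: the proteoglycan gene Hspg2, the metalloproteinase inhibitor gene Timp3 and the collagen gene Col18a1. Their adjusted p was 0.447 and 0.477 with an estimated correlation. Of 23 genes of TGF-beta and BMP signalling (camera adjusted p = 0.0183 and 0.0137), 0 were called and 4, adjusted over the list alone, rose with the block: Smad3, Bmp4, Bmp6 and Tgfb2. That list had adjusted p = 0.486 and 0.477 with an estimated correlation.

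With the block 3 more lists passed: VEGF response and angiogenesis (1 of 16 rose, Vegfc; camera adjusted p = 0.00938), endothelial-mesenchymal transition (1 of 9 rose, the transcription factor gene Zeb2, 29.4 to 49.9 CPM; camera adjusted p = 0.0142), and, lower, cytosolic ribosomal proteins (27 of 28 negative, 0 called; adjusted p = 0.0142). Their adjusted p was 0.477, 0.477 and 0.743 with an estimated correlation. Zeb2 itself had an edgeR adjusted p of 0.0483 with the block and missed the threshold in all 9 settings with libraries left out (0.146 to 0.666), Car4 in 6 of them and Vegfc in 3. The list of Tie2 receptor signalling, the pathway named in the series title, had 15 of 22 measured members positive, 0 called and 0 adjusted over the list alone (adjusted p = 0.0913 without and 0.0644 with the block; 0.577 with the block and an estimated correlation). Its adjusted p over all alternatives ran from 0.0106, with the block and without replicate number 2, to 0.577. Among its members Tie1 was at 261 CPM in WT and 287 CPM in Foxf2-ECKO and the nitric oxide synthase gene Nos3 at 238 and 268 CPM. Of 20 nitric oxide and vasoactive genes 1 rose (Edn1) and 0 fell, of 25 blood-brain barrier transporters 1 fell (Slc16a1) and 0 rose. Of 20 junction genes 0 changed, with the tight junction gene Cldn5 at 5124 CPM in WT and 4573 CPM in Foxf2-ECKO. In all, 6 lists passed without and 9 with the block, and 0 with an estimated correlation or by fry in either fit. Other splits of the 6 libraries into groups of 3 called up to 10 lists without a block. With the real split counted, 5 of 10 splits called at least 6.

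List calls also rested on libraries. The first values below are from the fit without a block, and the ranges in brackets cover alternatives with and without it. The TGF-beta and BMP list had an adjusted p of 0.0716 without WT replicate 1 and 0.228 without Foxf2-ECKO replicate 3 (range 0.00314 to 0.486). Capillary identity had 0.249 without Foxf2-ECKO replicate 1 and 0.169 without WT replicate 2 (range 1.68e-04, with the block, to 0.486). Mitochondrially encoded genes had 0.169, 0.125 and 0.161 without Foxf2-ECKO replicate 1, WT replicate 2 and WT replicate 3 (range 8.08e-07, with the block and without replicate number 1, to 0.576). Nuclear oxidative phosphorylation genes had 0.574 without WT replicate 2 and turned to higher without Foxf2-ECKO replicate 3 (0.970; range 4.74e-07 to 0.970). With the block, the TGF-beta and BMP list was lost without replicate number 3 (0.333), and VEGF response without number 2 (0.152) and number 3 (0.449). Endothelial-mesenchymal transition was lost without number 1 (0.0715) and number 2 (0.0665) and at an equal class mix (0.0883). Ribosomal proteins were lost without number 3 (0.811), at an equal class mix (0.254), without the unnamed cluster (0.951) and with the length trend removed (0.629), and the list turned to higher without number 3 and with the trend removed. Adjusted p over the blocked alternatives ran from 2.13e-04 to 0.477 for VEGF response, from 0.00900 to 0.477 for endothelial-mesenchymal transition and from 1.16e-04 to 0.951 for ribosomal proteins.

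The fourth comparison repeated the test in capillary-like cells, 3143 cells of a class rebuilt from fixed markers. Hebp1 fell from 41.6 ± 16.2 to 0.717 ± 0.622 CPM (SD, n = 3), with 0 UMIs in Foxf2-ECKO replicate 3. So did Pttg1, the securin gene (ENSMUSG00000020415, chromosome 11, 43420250 to 43426251), from 85.6 ± 21.7 to 11.1 ± 11.6 CPM, also with 0 UMIs there. These genes, Foxf2 and Cdkn2b (60.8 ± 9.08 to 21.8 ± 3.80 CPM) were the 4 genes of 8861 called without a block (edgeR adjusted p = 1.15e-05, 0.0185, 1.47e-04 and 0.0315), all lower in Foxf2-ECKO. With the block 16 genes passed, 3 higher and 13 lower. Edn1 rose from 382 ± 86.8 to 752 ± 188 CPM, a log2 fold change of 0.93 ± 0.13 (approximate SE; adjusted p = 2.64e-04), Unc13c from 47.1 ± 8.63 to 146 ± 93.6 CPM, and the cytochrome gene Cyp2e1 from 8.68 ± 3.57 to 53.7 ± 44.7 CPM. In Foxf2-ECKO replicates 1, 2 and 3 Cyp2e1 was at 34.7, 21.7 and 105 CPM (the last from 23 UMIs) and Unc13c at 115, 71.2 and 251 CPM. Without Foxf2-ECKO replicate 3 Cyp2e1 missed the threshold (adjusted p = 0.1001, log2 fold change 1.66 in place of 1.99), 1 of 6 such losses in 9 settings with libraries left out. Slc16a1, itself a marker used to name the class, fell from 530 ± 56.1 to 276 ± 34.3 CPM (log2 fold change -0.96 ± 0.13, adjusted p = 7.02e-05), and the carboxypeptidase gene Cpe from 96.3 ± 8.90 to 48.1 ± 20.4 CPM. Tek was at 605 ± 123 CPM in WT and 556 ± 142 CPM in Foxf2-ECKO (adjusted p = 1.00 in both fits).

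In capillary-like cells the fit without a block had 216 genes at an unadjusted p below 0.05 (443 expected by chance), DESeq2 called 6 genes and limma-voom 2. Hebp1, Pttg1 and Foxf2 stayed past the threshold of the blocked fit with any library left out, and 6 of the 9 named genes lost it without Foxf2-ECKO replicate 1, where the blocked count was 4 and Slc16a1 had an adjusted p of 0.0628 and Edn1 of 0.143. Without a block, Pttg1 missed it without Foxf2-ECKO replicate 1 (0.158), WT replicate 2 (0.102) and WT replicate 3 (0.132), and Cdkn2b without WT replicate 1 (0.216), Foxf2-ECKO replicate 1 (0.585), WT replicate 2 (0.285) and Foxf2-ECKO replicate 2 (0.0989). Their adjusted p over that fit's alternatives, the block among them, ran from 9.15e-13 to 0.161 for Pttg1 and from 4.16e-04, with the block, to 1.00 for Cdkn2b. Among the lists, 0 passed without a block and 5 with it: VEGF response (higher, adjusted p = 0.0251), leukocyte adhesion (higher, 0.0430), fenestrated identity (higher, 0.0457), capillary identity (lower, 0.0430) and mitochondrially encoded genes (lower, 8.97e-04), each with adjusted p = 0.488 with an estimated correlation.

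The fifth and sixth comparisons covered venous-like (346) and arterial-like (410) cells. In venous-like cells Slc16a1 fell with the block from 431 ± 142 to 202 ± 3.84 CPM (SD, n = 3; log2 fold change -1.16 ± 0.25, approximate SE; edgeR adjusted p = 0.00504), as did the glycoprotein gene Lrg1, from 315 ± 286 to 142 ± 35.9 CPM (adjusted p = 0.0382), and the predicted gene Gm10800, which lies outside the naming rule. Of the 3 genes called, only 1, Slc16a1, moved in the same direction in all 3 pairs, and Lrg1 did not. Lrg1 was at 644 CPM in WT replicate 1 and at 168 and 132 CPM in WT replicates 2 and 3, within the Foxf2-ECKO range of 116 to 183 CPM. Without WT replicate 1 its log2 fold change was -0.26 in place of -1.29 in the fit without a block. The adhesion molecule gene Icam1 (84.0 ± 54.5 in WT, 267 ± 245 CPM in Foxf2-ECKO, with 548 CPM in replicate 3), Nckap5, Cyp26b1, Qsox1, Dag1 and Hspa12b (106 ± 12.7 and 239 ± 48.1 CPM) did not pass, nor did Mgp, Pomp, Ndnf and Map3k1 (146 ± 13.7 and 62.5 ± 4.20 CPM) among genes with lower values. Without a block edgeR called 0 of 3352 genes (73 at an unadjusted p below 0.05; DESeq2 0, limma-voom 0), 2 without WT replicate 2 and 1 without WT replicate 3. Lists of venous-like cells passed with the block for ribosomal proteins (lower, camera adjusted p = 0.00554), immediate-early genes (lower, 0.0111; 0.0433 without a block) and VEGF response (higher, 0.0339), with adjusted p = 0.75 for each with an estimated correlation (0.738 for immediate-early genes without a block).

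In arterial-like cells 0 of 3413 genes passed in either fit (edgeR; 72 at an unadjusted p below 0.05 without and 173 with the block; DESeq2 0, limma-voom 0). In the fit with the block the smallest p belonged to Timp3, an inhibitor of matrix metalloproteinases. It was at 1851 ± 358 CPM in WT and 3113 ± 331 CPM in Foxf2-ECKO (SD, n = 3; log2 fold change 0.74 ± 0.13 with the block, edgeR adjusted p = 0.0612). Cacna1d was at 7.60 ± 7.57 and 78.6 ± 17.2 CPM, Foxf2 at 103 ± 26.8 and 36.1 ± 14.5 CPM, and Tmem100 at 473 ± 145 and 225 ± 61.0 CPM. Sema3c, Cped1, Cdh13 and Hmcn1 had higher and the selenium transport gene Selenop, Fry, Stxbp6 and Mylk lower values that did not pass. The count without a block became 2 without Foxf2-ECKO replicate 2 and 1 without WT replicate 2 or without both libraries of replicate number 2. Mitochondrially encoded genes (13 of 13 negative; camera adjusted p = 1.88e-05) and targets of SRF and YAP (14 of 18 negative; 0.0345) were lower with the block, with adjusted p = 0.786 with an estimated correlation.

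A genotype effect that differs between capillary-like, venous-like and arterial-like cells was tested in 5643 genes with the library as a block, and 0 passed (edgeR; 224 at an unadjusted p below 0.05; DESeq2 0). Hebp1 had the smallest p (adjusted p = 0.0871), with 95.6 ± 43.3 CPM in WT and 31.3 ± 13.8 CPM in Foxf2-ECKO arterial-like cells against 41.6 and 0.717 CPM in capillary-like cells and 30.4 and 0 CPM in venous-like cells. Hspa12b, Map3k1, Klhl4, Cped1 and Tmem252 followed (adjusted p = 0.118 each). Leaving out a library gave 2 genes without Foxf2-ECKO replicate 1, 4 without WT replicate 2, 3 without Foxf2-ECKO replicate 2 and 1 without WT replicate 3.

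The last comparison set the shares of cell classes side by side, which the sort on CD31 and against CD11b and CD45 can shift. Arterial-like cells were 7.61 ± 0.210% of endothelial cells in WT and 10.3 ± 2.48% in Foxf2-ECKO (SD, n = 3; exact permutation p = 0.3). Capillary-like cells were 64.9 ± 5.19% and 57.7 ± 11.4% (exact permutation p = 0.4), and venous-like cells 8.18 ± 2.75% and 8.36 ± 3.21% (exact permutation p = 0.9). A class of 888 low-depth cells without a name, led by Camk1d, Sdk1 and Unc13c, made up 17.2 ± 2.25% and 21.1 ± 3.48% (exact permutation p = 0.2). Fenestrated-like cells were 2.14 ± 1.44% and 2.55 ± 2.41% (exact permutation p = 1). Of all retained cells, pericytes were 5.69 ± 1.44% in WT and 4.04 ± 0.118% in Foxf2-ECKO (exact permutation p = 0.2), astrocytes 7.77 ± 11.7% and 12.7 ± 11.1%, oligodendrocytes 5.03 ± 5.75% and 5.60 ± 4.26%, and lymphocytes 5.10 ± 3.43% and 3.08 ± 3.39%. There were 8.90 ± 5.33 pericytes per 100 endothelial cells in WT and 6.25 ± 1.64 in Foxf2-ECKO (exact permutation p = 0.6). WT replicates 1, 2 and 3 had 14.9, 6.91 and 4.86 and Foxf2-ECKO replicates 1, 2 and 3 had 6.85, 4.39 and 7.51, so replicate number 3 ran the other way and WT replicate 1 alone lay above every Foxf2-ECKO library. No share passed (adjusted p of at least 0.667, two-sided, Benjamini-Hochberg), in a design whose smallest p is 0.1. Within replicate numbers, pericytes, lymphocytes and capillary-like cells had lower and unnamed and mixed cells higher shares in Foxf2-ECKO in all 3 pairs (exact sign-flip p = 0.25 each, the smallest possible). For capillary-like cells this p was 0.5 at halved resolution and without centring, for unnamed cells 1 without centring, and for pericytes 0.5 with doublets kept and at doubled resolution of all cells. Pericytes, whose cluster holds smooth muscle cells, were nearly level in replicate number 3, with 17 of 416 retained cells in WT and 16 of 396 in Foxf2-ECKO. The capillary-like difference of -7.18 points became -1.82 without Foxf2-ECKO replicate 3 and -13.2 without Foxf2-ECKO replicate 2, and the arterial-like difference of 2.69 points became 1.735 and 4.09.

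**Figure D3:**
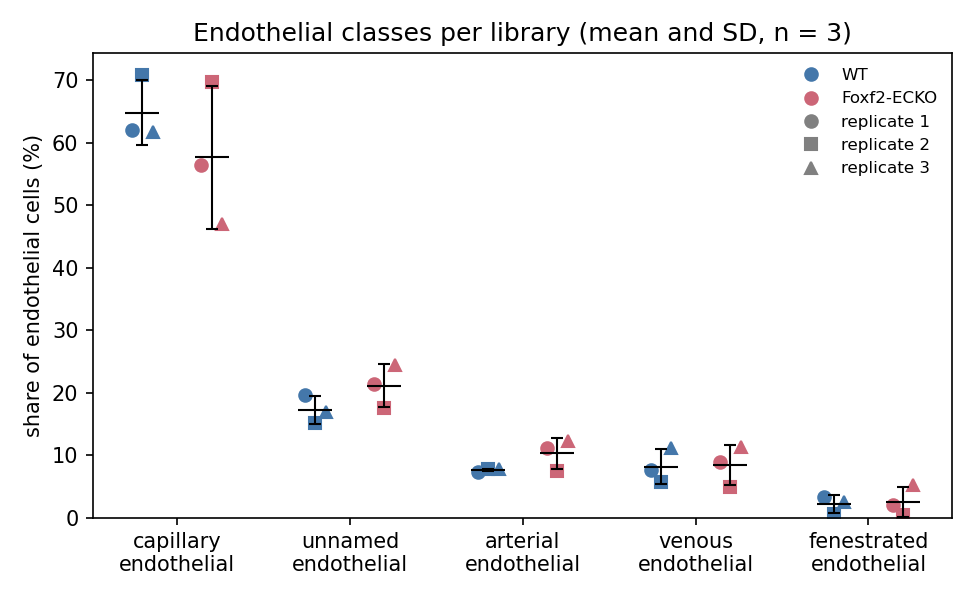
Share of each class among the endothelial cells of a library, in percent, with one point per library and bars for the mean and SD of 3 libraries. Capillary-like cells were the largest class in every library, and the WT and Foxf2-ECKO points overlapped in each class.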

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

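The table of Xist and Y-linked genes by hashtag, the reading of a split by endothelial share and the covariate for that share were chosen only after the results they examine had been seen. The 2 hashtag antibodies (HT1 and HT2), not used in the comparisons, gave 2339139 UMIs over the 6 libraries. They ranged from 26441 UMIs in WT replicate 3 to 795941 in Foxf2-ECKO replicate 1, with a median of 48 to 288 per cell. A retained cell was given a tag if its UMIs of that tag were more than 2 times those of the other, without background correction. In WT replicates 1, 2 and 3 this left 1528, 524 and 46 cells without a tag. In Foxf2-ECKO replicates 1, 2 and 3 it left 839, 1005 and 168. In WT replicate 1, 313 retained cells were given HT1 and 195 HT2. Xist, the RNA of the inactive X chromosome, was found in 52.4% of these HT1 cells and 9.23% of the HT2 cells, and Y-linked genes in 5.43% and 29.7%. In Foxf2-ECKO replicates 1, 2 and 3, Xist was found in 44.0%, 58.0% and 54.0% of HT1 cells and in 2.12%, 2.86% and 4.26% of HT2 cells. Y-linked genes were found there in 11.6%, 3.54% and 10.3% of HT1 cells and in 35.8%, 32.9% and 58.9% of HT2 cells. In WT replicates 2 and 3 nearly all cells given a tag had HT2 (976 and 369, against 10 and 1 with HT1). WT replicate 2 still held 86769 HT1 UMIs against 198718 of HT2, so the cut does not show that HT1 cells were absent. Xist was found in 28.5% and 22.8% of these HT2 cells and Y-linked genes in 25.6% and 27.4%. The labels do not say what the tags stood for, so cells were not split by tag. Tags that part cells of female and male animals would give the shares of WT replicate 1 and the Foxf2-ECKO libraries. Pooling of animals of both sexes in a library was not tested further. Of the sex-linked list, 6 genes were measured in endothelial cells (camera unadjusted p = 0.484 without and 0.260 with the block). This directional test can miss members that move opposite ways, so it does not show that the genotypes were balanced for sex.

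Other splits of the 6 libraries into groups of 3 were run for each count. With 10 splits, or 4 that part all 3 pairs, a share under 0.05 cannot be reached. Over all endothelial cells the real split called 2 genes and the highest other 42, with 2 of the 10 splits at least as large as the real one. In capillary-like cells the real split called 4 and the highest other 22 (2 of 10). In venous-like cells these were 0 and 12, in arterial-like cells 0 and 8, and for genotype by class 0 and 5 (10 of 10 in each). For the 26 lists they were 6 and 10 (5 of 10). With the block, among splits parting all 3 pairs, the real split called 51 genes over all endothelial cells and the highest other 5 (1 of 4). In capillary-like cells these were 16 and 2 (1 of 4). The split that called 42 and 22 genes sets WT replicate 1 and Foxf2-ECKO replicates 1 and 3 against the others. It points to a structure of the samples, whose cause was not tested. This split parts the WT and Foxf2-ECKO libraries of replicate number 3, so the block cannot remove the structure in that pair. Endothelial cells were 46.0 to 60.7% of retained cells in WT replicate 1 and Foxf2-ECKO replicates 1 and 3, and 84.1 to 89.2% in the others. With that share as a covariate and no block, genotype called 3 genes over all endothelial cells and 4 in capillary-like cells.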

How the results depend on the processing

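Of the alternatives, those of the blocked fits, leaving out the unnamed cluster, the length trend and the endothelial share as a covariate were added after the data were seen. The cause of the shifts below was not tested. The block raised the calls over all endothelial cells from 2 to 51, and whether to use it was settled after both counts had been seen, on a correlation of 0.117 in pair 1. It changed no call other than those the report gives. Differences in shares and in Foxf2 CPM could not move with it, since the mean of the paired differences equals the difference of the means. Of 111 gene values followed, 98 kept 1 sign in every setting and 13 did not. Of 5018 values, 5 were counted as reversed, which required a turn of sign and an adjusted p below 0.05 in the main or the other setting. Other turns of sign are not among the 5. Shares and counts of calls had no such label. Lists were held against the fit without a block, so the turns of the ribosomal list among the blocked alternatives are not counted either. Cpe had a log2 fold change of 0.22 over all deposited barcodes with the block. Fenestrated identity was lower without WT replicate 2 (camera adjusted p = 0.0350; without single libraries 0.00122 to 0.976). Nuclear oxidative phosphorylation genes were higher without Foxf2-ECKO replicate 3 (0.970; 4.74e-07 to 0.970), and so were ribosomal proteins (0.00249; 1.81e-06 to 0.477). Immediate-early genes were higher with the block and without replicate number 1 (2.45e-04; without other numbers lower, 1.73e-09 to 1.17e-04). The strict setting could not be run for venous-like cells, limma-voom and the block were not run for genotype by class, and halving the resolution gave no unnamed class.

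Without a filter on low counts the calls were 15 over all endothelial cells (102 with the block), 11 in capillary-like cells (47 with the block), 1 in arterial-like cells and 1 for genotype by class. DESeq2 called 4 over all endothelial cells and, with the block, 16 there and 6 in capillary-like cells. limma-voom called 2 in capillary-like cells. The block gave 51 calls over all endothelial, 16 in capillary-like and 3 in venous-like cells. All deposited barcodes gave 0 calls with and without the block and a Foxf2 difference of -69.3 CPM in place of -103. Stricter cells gave, with the block, 19 calls over all endothelial and 32 in capillary-like cells. For genotype by class they left venous-like cells of only 1 library per genotype, so that count is not given. Thinned libraries gave 25 and 5 with the block and 2 in capillary-like cells without it. An equal class mix gave 26 with the block, the length trend removed 5 without it, and doublets kept 1 for genotype by class. An estimated correlation and fry gave 0 lists with and without the block. Without centring the unnamed share differed by -0.248 points in place of 3.90. Without thinning of cells the share with a Foxf2 UMI differed by -17.3 points.

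With libraries left out the calls were 0 to 5 over all endothelial cells, 7 to 101 with the block, 2 to 5 in capillary-like cells, 4 to 20 with the block, 0 to 2 in venous-like and in arterial-like cells, and 0 to 4 for genotype by class. Lists numbered 4 to 10. Class shares differed by -13.2 to -1.82 points for capillary-like, 1.735 to 4.09 for arterial-like and 2.25 to 5.71 for unnamed cells. The difference turned sign for venous-like (-1.27 to 1.91) and fenestrated-like cells (-0.892 to 1.47). Foxf2 differed by -108 to -93.8 CPM and by -8.65 to -7.31 points of cells with a UMI.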

Other observations

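The tests in other cell types, within capillary-like cells, without the unnamed cluster and of gene length were chosen only after the calls they examine had been seen. Slc16a1 stood at 41.8 CPM in WT and 40.3 CPM in Foxf2-ECKO over non-endothelial cells pooled (ratio 0.965, exact 95% interval 0.753 to 1.23), against 491 and 235 CPM in endothelial cells (ratio 0.479, 0.447 to 0.514). Edn1 stood at 4.69, 8.94 and 0 CPM in non-endothelial cells of WT replicates 1, 2 and 3 and at 28.1, 26.3 and 1.27 CPM in those of Foxf2-ECKO. Pooled, these cells gave a ratio of 4.15 (exact 95% interval 2.45 to 7.31, from 20 and 55 UMIs), against 1.62 (1.54 to 1.70) in endothelial cells. Edn1 was thus higher outside endothelial cells too, at levels far below its pooled 483 and 782 CPM in endothelial cells. Edn1 and Foxf2 both lie on chromosome 13, and a background difference at Edn1 was not tested. Unc13c was at 371 and 253 CPM in pericytes and at 142 and 182 CPM in astrocytes. These are pooled counts without a test between libraries.

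Markers of cell types were also run as lists over endothelial cells. With the block, arterial markers were higher (camera adjusted p = 3.44e-04) and capillary markers lower (0.00136), each with adjusted p = 0.753 with an estimated correlation. Endothelial, venous, interferon-responsive and astrocyte markers were not called (adjusted p = 0.457 each), nor were fenestrated (0.625), tip-like (0.704) and erythroid markers (0.906). The other 13 of the 22 lists, neuron markers among them, had fewer than 3 measured members. Neuronal RNA in endothelial droplets, as a source of called genes such as Bc1, was therefore not tested. The 3 erythroid genes had a median log2 fold change of -3.41 with the block, with the haemoglobin gene Hbb-bs at 111 CPM in WT and 12.2 CPM in Foxf2-ECKO.

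Hebp1, Pttg1 and Cdkn2b were lower in capillary-like cells of the Foxf2-ECKO libraries, and if the groups of animals differed in genetic background at these genes, the genes would be lower in non-endothelial cells too. Pttg1 had a ratio of 0.410 there (exact 95% interval 0.30 to 0.554), which such a difference could give, as could an effect of the genotype outside endothelial cells. For Hebp1 (0.561, 0.404 to 0.769) and Cdkn2b (0.431, 0.0437 to 2.27; 7 and 2 UMIs) the intervals reach past the bound of 0.75 set for the test, so a background difference cannot be told apart from an effect in endothelial cells. These counts are pooled, and the intervals hold counting error alone and no spread between libraries, so they cannot settle the question for any of these genes. In replicate number 2 Hebp1 was at 13.4 CPM in WT and 21.9 CPM in Foxf2-ECKO non-endothelial cells and Pttg1 at 64.8 and 57.0 CPM. Hebp1 was at 92.7 and 48.6 CPM in oligodendrocytes, which made up 0.846 to 11.6% of retained cells in a library. Endothelial RNA in other droplets was not tested as a source, and the animals' genotypes elsewhere were not analysed here.

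Arterial identity genes were higher and capillary identity genes lower over summed endothelial cells (each adjusted p = 0.477 with the block and an estimated correlation). With each class at the same share in every library both lists still passed with the block (camera at the preset correlation, larger adjusted p = 0.0113). Without a block, that setting passed at least as many lists in 5 of 10 splits of the libraries, the real one included. An estimated correlation was not run at the equal mix. The lists' passing therefore cannot decide whether the mix caused the calls. The median log2 fold change shrank from 0.25 to 0.10 for arterial and from -0.07 to -0.02 for capillary identity, so the mix may give much of the shift. Within capillary-like cells the larger adjusted p was 0.0547, for the arterial list, beside 0.0430 for the capillary list, with a capillary median of -0.00, so a mix of cells inside the class may remain. A shift of cell state by genotype stays open and was not tested.

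The 26 genes higher with the block were long, with a median span of 236 kb against 26.9 kb for tested genes, above 100% of 10000 sets matched on expression. The 25 lower genes were short, with a median of 15.1 kb, above 1.4% of such sets. Without the low-depth unnamed class the median log2 fold change went from 0.75 to 0.72 (SD over genes 0.30), which argues against that class as the whole cause. All 26 kept their sign and 23 an unadjusted p below 0.05. These genes were called on sums that share most of the same cells, so those counts are a weak test. With fewer cells summed only 14 of the 26 kept an adjusted p below 0.05. With each library's trend on gene span removed, 16 kept an adjusted p below 0.05 and the median log2 fold change went to 0.68. A length trend between libraries may therefore underlie part of the pattern and cannot be told apart from an effect of the genotype by this test, and a difference in unspliced RNA was not tested.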
